A study of Mus musculus with 12 samples.

How the data were processed

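Total RNA from the testis of male C57BL/6 mice aged 4 months was sequenced as small RNA libraries of 17 to 40 nt, before and after oxidation with sodium periodate, at inputs of 10, 50 and 100 ng with 2 technical replicates each (12 libraries, 6 groups). Per the labels, spike-in RNA was added in proportion to the input, and no batch or day is given. The authors' processing notes name Bowtie, without a version, and the builds mm10 and hg38; what hg38 was used for is not given in the sources used here.

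The deposited miRNA and piRNA tables hold RPM values. The deposited spike-in table holds raw read counts, with 1 blank line that was left out. The denominator of the RPM values is not stated, so it was recovered from the step that 1 read makes in the piRNA values. In every library 100% of the piRNA values were whole reads within 0.01 of a read, and 93.24% to 100% of the miRNA values were, with all of the latter in sixths of a read, as from reads shared between miRNAs. The recovered denominators were 1924201 to 3347735 reads and did not include the spike-in reads. A count of 3 reads in 1 library, taken as the floor, was worth 0.896 to 1.56 RPM. For a miRNA at 0 in all 6 libraries after oxidation the floor was 3 reads over these libraries. No per-sample column was left unused.

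Features with a mean of at least 5 RPM were tested, 141 miRNAs of 1915 names and 22726 piRNA sequences of 1018402. The log2(RPM + 1) values were fitted with limma-trend (limma 3.58.1, R 4.3.3) to 6 group means with a shared spread. The contrasts were after against before oxidation (averaged over inputs and at each input), 10 and 50 ng against 100 ng before and after oxidation, and the interaction of oxidation with input (moderated F test, and 10 against 100 ng alone). A feature was called at a Benjamini-Hochberg adjusted p below 0.05. Fixed miRNA lists were tested with camera (preset correlation of 0.01, and an estimated one) and fry, adjusted over the lists, and lists with fewer than 3 tested members were given by their members. Lists were the let-7, miR-34 and miR-449, miR-17-92, miR-290-295, miR-30, miR-29, miR-10, miR-99, miR-100 and miR-125 and miR-15/16 families, the X-linked, miR-183/96/182 and Dlk1-Dio3 clusters, miRNAs of Sertoli and other gonadal somatic cells, blood cells, vessel and muscle, and liver, and atypical miRNAs. List members were also adjusted over the list alone.

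Class totals, spike-in values, composition and detection were tested by exact 2-sided permutation of the oxidation labels within inputs, adjusted over each family of values. The smallest p these permutations can give is 0.00926. Shares of spike-in reads carry exact binomial 95% intervals. Correlations between libraries were computed across features and carry no p. The replicates being technical, no p refers to differences between mice.

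The miRNAs named in the text were chosen by a rule written before the data were examined, among those with a mean of at least 10 RPM. They were the 10 highest before oxidation, the 8 largest falls, the 8 largest rises (or highest log2 fold changes) among those called and moved the same way in all 6 pairs, the 2 highest members of each list and the 3 with the smallest interaction p. For the rises no miRNA met the condition on pairs, so the 8 highest log2 fold changes were taken. For piRNA sequences it was the 4 highest before oxidation, the 4 largest falls and the 4 largest rises. Tested piRNA sequences were matched without mismatch to the transcripts of GENCODE M21 on both strands. No genome sequence was searched, so sequences from unannotated loci have no position here.

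The alternatives chosen before the data were examined were pseudocounts of 0.1 and 10, no filter and a filter of 50 RPM, centring on library medians, quantile normalization, scaling to all spike-in reads, edgeR (4.0.16) with TMM, DESeq2 (1.42.0), an added limit of 1 on the absolute log2 fold change, a replicate block, fits on only the 4 libraries compared, and leaving out each library in turn. Scaling to methylated spike-ins alone, edgeR without TMM, a spread per group, thinning to 1600000 piRNA reads, piRNA totals over the reads other than miRNA reads and an estimated correlation on centred values were added after seeing the data. Both count tools were run on reads rounded to whole numbers. The tests were also run on simulated data, drawn in every library from the mean of each feature over all 12 libraries. Simulated miRNA levels after oxidation were thus far above the real ones, which came from 625 to 937 miRNA reads per library. The recovered shares of miRNAs below do not describe such low counts. With changes of 1.5-fold, 2-fold and 4-fold in the contrast averaged over inputs, limma-trend recovered 50%, 84.6% and 100% of changed miRNAs and 3%, 7.5% and 54.5% of changed piRNA sequences. Changes were given to 40 of 141 miRNAs and 200 of 22726 piRNA sequences, smaller shares than were called in the real data. The cut-off of the adjusted p depends on this share, so the recovered shares of piRNA sequences do not describe the real contrast. With no change limma-trend called 1089 piRNA sequences at 10 ng and 1122 between 10 and 100 ng after oxidation. In these comparisons edgeR without TMM called 797 and 793, and a spread per group called 0 in both. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.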

Results

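Small RNAs of 17 to 40 nt were sequenced from testis total RNA of male C57BL/6 mice aged 4 months, before and after oxidation with sodium periodate (NaIO4). Periodate oxidizes an RNA 3' end that carries free 2' and 3' hydroxyls and so blocks adapter ligation, whereas an end with a 2'-O-methyl group is left intact. Most mammalian miRNAs end in free hydroxyls. The piRNAs, which guide PIWI proteins in germ cells, carry a 2'-O-methyl group added by the methyltransferase HENMT1. Libraries were made from 10, 50 and 100 ng of RNA before and after oxidation, with 2 technical replicates in each of the 6 groups (12 libraries). The replicates were technical, so all p-values measure the spread between libraries and not between mice. The first comparison asks which small RNAs withstood oxidation, and the series of inputs asks how this depended on the amount of RNA.

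The deposited tables held abundances scaled to library size (RPM) for 1915 miRNA names and 1018402 piRNA sequences, and read counts for 6 spike-in RNAs. The RPM values corresponded to denominators of 1924201 to 3347735 reads per library. Before oxidation they were 2799596 and 2754411 reads at 10 ng, 2578922 and 3347735 at 50 ng and 2965389 and 3280001 at 100 ng. After it they were 2162327 and 1924201 at 10 ng, 2866316 and 2246199 at 50 ng and 3347004 and 3166360 at 100 ng. Reads assigned to miRNAs numbered 326701 to 454158 per library before oxidation and 625 to 937 after it. A count of 3 reads was worth 0.896 to 1.56 RPM in a single library. Intervals and floors cover counting error only.

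After oxidation nearly all miRNA reads were gone, and most of the remaining reads were piRNA reads. Summed miRNA abundance was 128190 ± 8611 RPM before oxidation and 303 ± 74.7 RPM after it (SD, n = 6 each). Averaged on the log scale the fall was 433-fold, and it was 329-fold at 10 ng, 502-fold at 50 ng and 491-fold at 100 ng. Summed piRNA abundance rose 1.13-fold in RPM, from 805481 ± 7700 to 909880 ± 14873, but fell against the methylated spike-ins, which are described with their values further on. The number of piRNA reads per miRNA read went from 6.31 ± 0.49 to 3151 ± 720. Each of these changes went the same way in all 6 pairs of same-numbered libraries and gave p = 0.00926 in a 2-sided exact permutation test within inputs. That is the smallest p this test can give, and it stayed at 0.00926 after Benjamini-Hochberg adjustment over the 3 values. RPM is a share of a total that includes the miRNA reads, so their loss by itself raises the RPM of all other reads. As a share of the reads other than miRNA reads, piRNA reads went from 92.4% ± 0.0732 to 91.0% ± 1.48 (n = 6, exact permutation p = 0.00926), so the direction of the piRNA total turned from a rise to a fall.

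**Figure D1:**
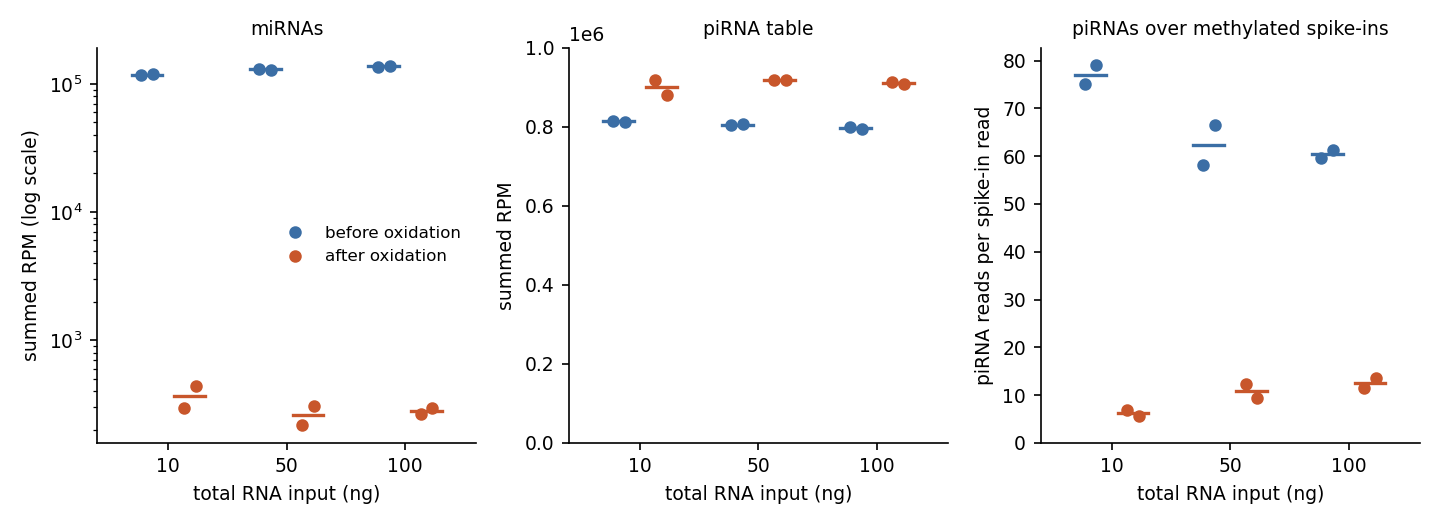
Summed miRNA RPM (left, log axis), summed piRNA RPM (middle, linear axis) and piRNA reads per methylated spike-in read (right, linear axis) before and after oxidation at 10, 50 and 100 ng. Points are libraries and lines are means of 2. All miRNA totals after oxidation lie at or below 441 RPM, against at least 116696 RPM before it, while the piRNA totals stay between 795481 and 919539 RPM.

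The most abundant miRNAs before oxidation came largely from the X-linked testis cluster and the family of miR-10, miR-99, miR-100 and miR-125 (miR-10 and miR-125 family), and all of them fell. The highest was miR-741-3p of the X-linked cluster (Mir741, GRCm38 chromosome X, 66796805 to 66796875, minus strand), at 28160 ± 5817 RPM before and 25.5 ± 8.11 RPM after oxidation (n = 6). It was followed by miR-143-3p, an miRNA of smooth muscle (Mir143, chromosome 18, 61649196 to 61649258, minus strand), at 11550 ± 2037 and 11.7 ± 4.81 RPM, and by miR-10b-5p from the Hoxd cluster (Mir10b, chromosome 2, 74726070 to 74726137, plus strand), at 11090 ± 934 and 9.84 ± 4.05 RPM. The next were miR-100-5p (8103 to 5.55 RPM), miR-99a-5p (6121 to 4.43 RPM), miR-191-5p (6011 to 5.89 RPM) and miR-470-5p (5860 to 4.12 RPM). The last of the 10 were miR-871-3p (4420 to 4.63 RPM), miR-743b-3p (4321 to 2.62 RPM) and miR-99b-5p (3628 to 4.53 RPM). These 10 held 69.6% of the miRNA RPM before oxidation.

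**Figure D2:**
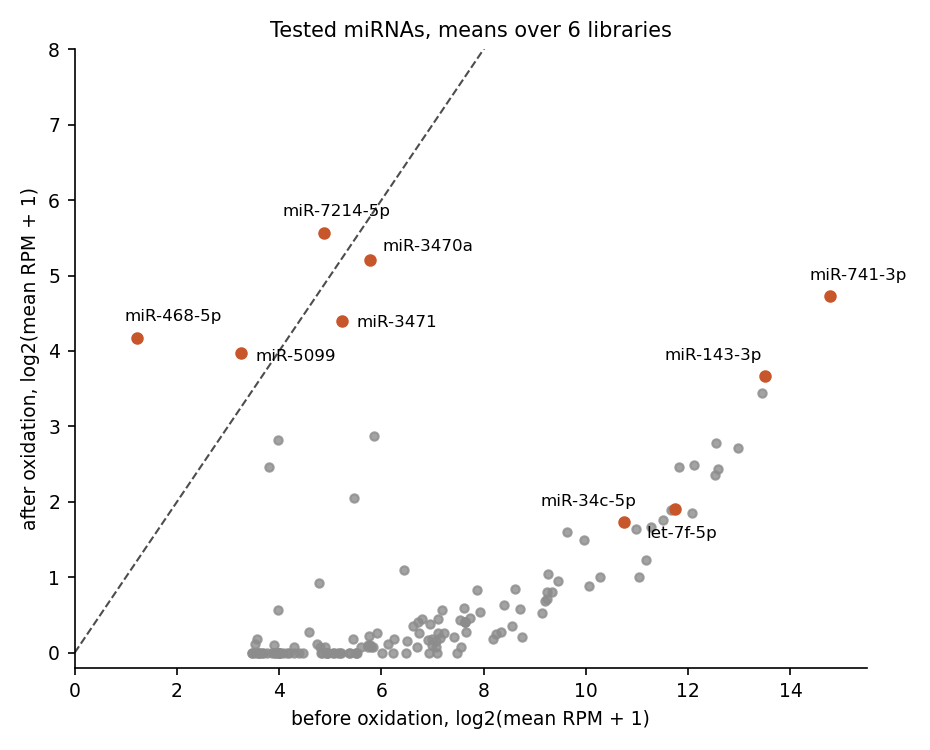
Mean RPM after oxidation against mean RPM before it for the tested miRNAs (n = 6 libraries on each axis, both axes as log2(mean RPM + 1), dashed line at equal values). Most miRNAs lie far below the line of equal values, and a few named entries, such as miR-7214-5p at 28.4 and 46.4 RPM, lie near it.

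Of the 141 miRNAs tested, 137 fell and 2 rose on oxidation averaged over inputs (limma-trend on log2(RPM + 1), Benjamini-Hochberg adjusted p below the threshold of 0.05). Among them, 134 fell in all 6 pairs. Chance alone moves 3.125% of unselected features the same way, up or down, in all 6. The 134 were called in the same libraries and replicate numbers do not pair them, so this count is not separate support. The largest falls on the log2(RPM + 1) scale were those of miR-100-5p (-10.27 ± 0.17, SE), miR-470-5p (-10.26 ± 0.24), miR-743b-3p (-10.24 ± 0.17) and miR-99a-5p (-10.11 ± 0.16), with adjusted p of 6.87e-12, 5.62e-11, 7.59e-12 and 6.86e-12 by limma. They were followed by miR-741-3p (-10.08), miR-10b-5p (-10.07), miR-148a-3p (2116 to 1.01 RPM, -10.06) and let-7g-5p (2297 to 1.34 RPM, -9.96). The 20 miRNAs with the highest RPM before oxidation fell by 740-fold to 2087-fold in RPM, with a median of 1208-fold. By input, 136 miRNAs fell at 10 ng, 135 at 50 ng and 134 at 100 ng, and 2, 1 and 0 rose. The fall was common to almost all miRNAs in RPM, and the number of calls depended on the scaling. Centring, quantile normalization, TMM and DESeq2 take out some or all of a loss that most features share. The median log2 fold change was -6.02 in RPM, 0.19 after centring, -0.16 after quantile normalization, -4.16 by edgeR with TMM (quartiles -7.34 and -0.79), 0.73 by DESeq2, -7.43 with all spike-ins and -7.61 with methylated ones. By edgeR with TMM, miRNAs such as miR-127-3p (-10.48) and miR-182-5p (-9.79) kept a large fall without a call. After centring of each library on its median, 69 rose and 60 fell, with 36 and 46 after quantile normalization, 8 and 13 by edgeR with TMM and 19 and 8 by DESeq2, whereas both spike-in scalings gave 0 rising and 140 falling. At 10, 50 and 100 ng in turn, centring gave 63, 65 and 60 rising against 58, 52 and 55 falling, quantile normalization 29, 30 and 31 against 19, 29 and 27, edgeR with TMM 8, 11 and 10 against 1, 9 and 9, and DESeq2 11, 22 and 20 against 3, 0 and 7.

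Every tested member of the X-linked testis cluster and of the larger miRNA family and cluster lists fell in RPM, in the same numbers when adjusted over the list alone. In the X-linked testis cluster, 24 of 24 members fell, from a sum of 46280 ± 3172 RPM to 40.4 ± 8.88 RPM (n = 6). The -3p arms of miR-465a, miR-465b and miR-465c in it held identical values, so their shared reads cannot be assigned. In the let-7 family, regulators of differentiation, 9 of 9 fell, from 12607 ± 1186 to 10.3 ± 3.24 RPM, with let-7f-5p at 3445 and 2.74 RPM and let-7a-5p at 2909 and 2.39 RPM. In the miR-10 and miR-125 family, 7 of 7 fell, from 31837 ± 3883 to 26.8 ± 8.08 RPM. In the family of miR-34 and miR-449, which acts in spermatocytes and spermatids, 4 of 4 fell, from 1881 ± 486 to 2.50 ± 1.19 RPM. Its leading members were miR-34c-5p at 1710 ± 491 and 2.31 ± 1.35 RPM and miR-34b-3p at 126 RPM before and 2 reads in total after oxidation. In the miR-17-92 and paralogous clusters, which drive proliferation, 6 of 6 fell, with miR-92a-3p at 997 and 1.81 RPM and miR-25-3p at 211 and 0.376 RPM. In the miR-30 family, 8 of 8 fell, with miR-30a-5p at 2017 and 2.12 RPM and miR-30c-5p at 790 and 2.03 RPM.

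The smaller lists and the lists of other cell types moved in the same way. In the miR-15/16 family 4 of 4 fell, with miR-16-5p at 106 and 0.199 RPM and miR-15b-5p at 103 RPM before and 1 read after. Of the Sertoli and gonadal somatic list 8 of 8 fell, from 650 ± 122 to 1.93 ± 1.70 RPM, with miR-27b-3p at 232 and 0.785 RPM and miR-24-3p at 171 RPM and 2 reads. Of the vessel and muscle list 4 of 4 fell, with miR-143-3p above and miR-145a-3p, its cluster partner, at 136 ± 19.7 RPM before and 0 reads after, at least 712-fold lower against a floor of 3 reads over the 6 libraries. Of the Dlk1-Dio3 cluster, an imprinted locus, 4 of 4 fell, with miR-127-3p at 121 RPM and 0 reads (at least 636-fold lower) and miR-541-5p at 52.1 RPM and 1 read. Lists with fewer than 3 tested members gave miR-183-5p (132 RPM, then 2 reads), miR-182-5p (74.2 RPM, then 0 reads, at least 388-fold lower), miR-29a-3p (27.4 RPM, then 0 reads, at least 144-fold lower), the liver miRNA miR-192-5p (243 and 0.458 RPM) and the atypical miR-320-3p (14.7 RPM, then 0 reads). No member of the miR-290-295 cluster or of the blood cell list passed the filter. No list fell more than the other miRNAs by camera (adjusted p of 0.29 for the X-linked cluster and 0.96 for each other list, and 0.96 for all lists with an estimated correlation), while fry called all 10 tested lists lower.

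After centring, 7 of 7 members of the miR-10 and miR-125 family and 7 of 9 of the let-7 family were called lower. Camera on the centred values gave these families adjusted p = 0.00871 and 0.0361 with the preset correlation, and adjusted p = 0.15 for both with an estimated correlation. The medians of these families and of the X-linked cluster were below 0 under all 7 other scalings or count models, though that of the X-linked cluster was only -0.01 by DESeq2. The direction turned positive after centring for the miR-34, miR-17-92, miR-15/16, Sertoli and Dlk1-Dio3 lists and for miR-29a-3p and miR-320-3p. It turned positive after quantile normalization for the Sertoli and Dlk1-Dio3 lists, miR-29a-3p and miR-320-3p, and by DESeq2 for these, the miR-34, miR-17-92, miR-15/16, miR-30 and vessel and muscle lists. These signs do not order the lists by their loss, since on the log2(RPM + 1) scale the fall of a miRNA near 0 reads after oxidation is limited by its level before it.

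A few miRNA entries kept much of their level after oxidation. No called miRNA rose in all 6 pairs, so the 8 with the highest log2 fold changes among those with a mean of at least 10 RPM are given here. Together they held 44% of the miRNA RPM after oxidation. The highest was miR-7214-5p (Mir7214, chromosome 17, 27317035 to 27317095, minus strand), at 28.4 ± 10.0 RPM before and 46.4 ± 25.3 RPM after oxidation (n = 6), a log2 fold change of 0.62 ± 0.27 (SE) with a limma adjusted p of 0.0484 and a rise in 4 of 6 pairs. Next, miR-5099 had 8.49 ± 2.96 and 14.8 ± 8.68 RPM (limma adjusted p = 0.449, higher in 5 of 6 pairs) and miR-3471 had 36.6 ± 8.28 and 20.1 ± 10.8 RPM (adjusted p = 0.0571, lower in 6 of 6 pairs). The fall of miR-3470a was from 53.7 ± 6.25 to 36 ± 31.0 RPM (adjusted p = 0.0431, lower in 5 of 6 pairs), and that of miR-3470b from 14.8 ± 5.80 to 6.06 ± 6.57 RPM (adjusted p = 0.0348, 5 of 6 pairs). Of the 139 called miRNAs, these last 2 and miR-7214-5p lost the call when 1 library was left out. The call of miR-7214-5p was lost in 10 of 12 such fits (log2 fold change 0.36 to 0.87) and kept only without the first replicate after oxidation at 10 or 50 ng. That of miR-3470a was lost in 9 (-1.47 to -0.57) and kept without the second after oxidation at 10 ng or either at 50 ng, and that of miR-3470b was lost in 10 (-2.25 to -1.04) and kept without the second at 10 or 50 ng. With a pseudocount of 0.1 the limma adjusted p of miR-7214-5p, miR-3470a and miR-3470b were 0.0929, 0.0681 and 0.0581, and without a filter they were 0.0597, 0.0573 and 0.05002. Larger falls were those of miR-7217-3p (57.2 ± 29.2 to 6.35 ± 4.31 RPM), miR-3535 (43.3 ± 5.44 to 3.14 ± 3.05 RPM) and miR-151-3p (23.1 ± 23.3 to 0.211 ± 0.516 RPM). Outside this rule, and chosen after its values were seen, miR-468-5p was the other entry that rose, from 1.33 ± 0.92 to 17.1 ± 16.1 RPM (log2 fold change 2.40 ± 0.39, adjusted p = 0.000243, higher in 5 of 6 pairs). Scaled to the methylated spike-ins, no miRNA was called as rising, and the log2 fold changes of miR-7214-5p and miR-5099 were -2.27 and -2.06.

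The spike-in RNAs, added in proportion to the RNA input as 3 sequences each with and without a methylated 3' end, separated in the same direction. Unmethylated spike-ins fell from 4123 to 15750 reads per library before oxidation to 7 to 25 reads after it, while methylated ones rose from 28325 to 42523 reads to 212579 to 300939 reads. Methylated reads per unmethylated read went from 4.38 ± 2.01 to 23391 ± 14996 (n = 6). Before oxidation the unmethylated share of spike-in reads increased with input, from 11.94% (95% exact binomial interval 11.6 to 12.3) and 13.47% (13.1 to 13.8) at 10 ng, to 21.88% (21.5 to 22.3) and 22.3% (21.9 to 22.7) at 50 ng, and to 26.74% (26.4 to 27.1) and 27.03% (26.7 to 27.4) at 100 ng. After oxidation it was between 0.0023% and 0.0118% in all 6 libraries. One methylated spike-in, sp2Me, held most spike-in reads in every library.

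Measured against the methylated spike-ins, both RNA classes fell. The number of piRNA reads per methylated spike-in read went from 66.6 ± 8.65 to 9.88 ± 3.15 (n = 6), a log2 change of -2.81. This change was -3.64 at 10 ng, -2.53 at 50 ng and -2.28 at 100 ng. Per sp1Me, sp2Me and sp3Me read the log2 change was -4.10, -2.83 and -2.13. The number of miRNA reads per methylated spike-in read changed by -11.75 on the log2 scale. All of these spike-in changes had p = 0.00926 in the exact permutation test within inputs, the smallest it can give, and an adjusted p of 0.00926 over the 12 spike-in values. The rise of the methylated spike-ins relative to mapped reads was unequal, at 92.3-fold, 13.6-fold and 15.8-fold for sp1Me, sp2Me and sp3Me at 10 ng, 14.7-fold, 6.75-fold and 2.95-fold at 50 ng, and 5.62-fold, 5.66-fold and 2.63-fold at 100 ng.

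**Figure D3:**
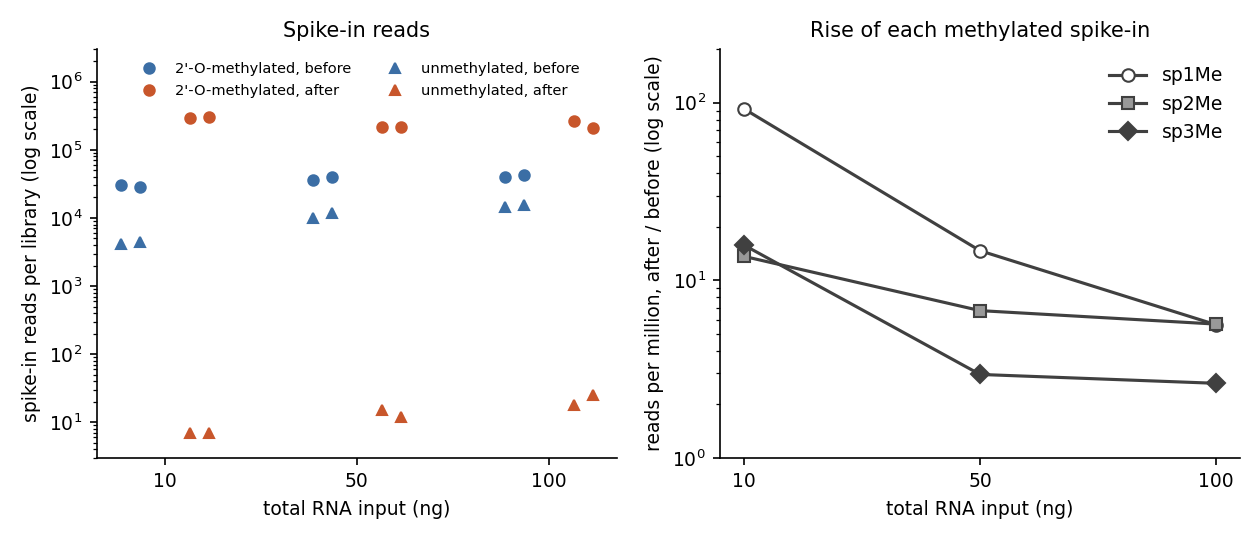
Left, reads of unmethylated and methylated spike-in RNAs before and after oxidation at 10, 50 and 100 ng, with one point per library and class. Right, the ratio of reads per library depth after to before oxidation for each methylated spike-in. Both vertical axes are on a log scale. Unmethylated spike-ins drop to between 7 and 25 reads after oxidation and methylated ones rise to between 212579 and 300939 reads.

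The length profile of the piRNA table kept its peak at 30 nt, a length typical of pachytene piRNAs, while the shares over 32 nt and at 19 nt fell. Sequences of 29 to 32 nt made up 64.1% ± 0.95 of piRNA RPM before and 65.9% ± 2.26 after oxidation (n = 6, exact permutation p = 0.0278, adjusted p = 0.0333). Sequences of 26 to 28 nt went from 23.7% ± 0.74 to 22.8% ± 0.76, and those over 32 nt from 2.71% ± 0.15 to 1.24% ± 0.35 (adjusted p = 0.0139 each, permutation test). The share under 26 nt was 9.43% ± 0.36 and 10.1% ± 1.86 and did not differ beyond the spread (exact permutation p = 0.306). Reads starting with U, the first base preferred by most PIWI-bound RNAs, went from 88.5% ± 0.07 to 90.0% ± 0.49, and reads with A at base 10, a mark of ping-pong amplification, from 33.9% ± 0.21 to 32.6% ± 1.12 (adjusted p = 0.0139 each over the 6 classes, permutation test). Among single lengths, the share at 19 nt fell from 1.03% ± 0.03 to 0.557% ± 0.155, while 17 nt rose from 0.288% to 0.635%, 20 nt from 0.402% to 0.658%, 22 nt from 0.733% to 1.09% and 30 nt from 25.2% to 26.9%. The share at 35 nt fell from 0.330% to 0.0679%. Each of these single lengths had an adjusted p of 0.0131 over 24 lengths (permutation test). Counted over distinct sequences without weights, the share under 26 nt fell by 4.57 percentage points and that of 26 to 28 nt rose by 0.70. Among sequences of at least 5 RPM the change at 29 to 32 nt was 0.16 points (exact permutation p = 0.380) and that under 26 nt was 2.34.

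**Figure D4:**
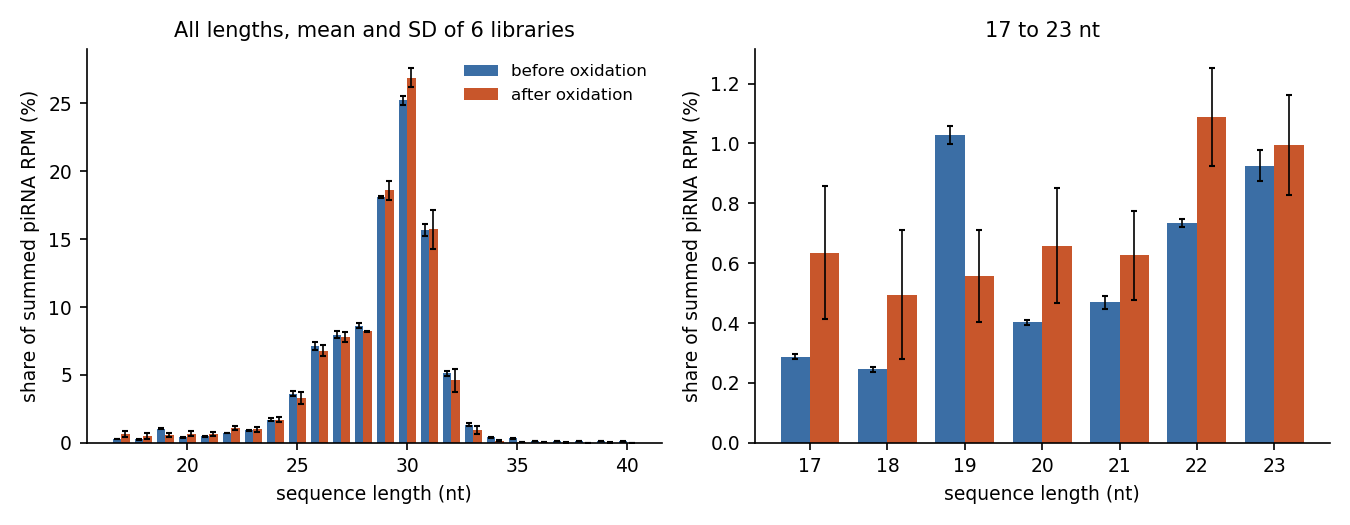
Percent of piRNA RPM at each sequence length from 17 to 40 nt, before and after oxidation. Bars are means of 6 libraries with SD, and the right panel enlarges 17 to 23 nt. Both profiles peak at 30 nt, at 25.2% before and 26.9% after oxidation, and the 19-nt share drops from 1.03% to 0.557%.

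Individual piRNA sequences moved both ways. Of 22726 sequences with a mean of at least 5 RPM, which held 64.0% of piRNA RPM, 4829 rose and 5179 fell on oxidation averaged over inputs (limma-trend, adjusted p below 0.05). Of these, 3437 rose and 2425 fell in all 6 pairs. By length, 45 rose and 64 fell among 124 sequences of 19 nt, and 441 and 357 among 1617 of 17, 18 and 20 to 25 nt. At longer lengths these were 785 and 1352 among 5713 of 26 to 28 nt, 3544 and 3256 among 14973 of 29 to 32 nt, and 14 and 150 among 299 over 32 nt. The most abundant before oxidation was TATGTGAATTTCAACTGTTGGCTCCACAGG (GRCm38 chromosome 7, 73824992 to 73825021, plus strand, exon 1 of the lincRNA Gm21269), at 5128 ± 1321 RPM before and 5375 ± 1883 RPM after (n = 6, limma adjusted p = 0.662). TACCTCGGTCTCTGTAGAATCCAGTTTTT, which matched no annotated transcript, fell from 3054 ± 705 to 2086 ± 1090 RPM (log2 fold change -0.72 ± 0.11, limma adjusted p = 0.000606, lower in 6 of 6 pairs). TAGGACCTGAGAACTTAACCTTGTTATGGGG, also without a match, had 2798 ± 1080 and 3401 ± 2096 RPM (adjusted p = 0.696, limma). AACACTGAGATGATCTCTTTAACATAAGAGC (chromosome 2, 127692460 to 127692490, plus strand, exon 1 of the non-coding Gm14244) had 2409 ± 674 and 3162 ± 2150 RPM (adjusted p = 0.754, limma).

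The largest falls with the same direction in all 6 pairs were outside the usual piRNA lengths. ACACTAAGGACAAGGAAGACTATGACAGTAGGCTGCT (37 nt) went from 134 ± 12.2 to 0.0742 ± 0.182 RPM and CTAGAGGCTTGGAAATGAC (19 nt) from 115 ± 25.7 to 0.0771 ± 0.189 RPM. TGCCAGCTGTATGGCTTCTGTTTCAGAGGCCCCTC (35 nt) went from 559 ± 16.5 to 8.41 ± 7.63 RPM. GCCCTGGCTGTCCTGGAAC (19 nt), which matched transcripts of 1557 genes, went from 101 ± 20.5 to 0.235 ± 0.395 RPM. The largest rises were CCCCACGTTGGGCGCCA (17 nt, antisense to transcripts of BC048559 and Vmn2r-ps104), from 0.412 ± 0.694 to 191 ± 230 RPM, and 3 sequences of 30 nt without a transcript match. These were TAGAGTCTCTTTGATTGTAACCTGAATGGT (0.107 to 78.4 RPM), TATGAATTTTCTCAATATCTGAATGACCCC (4.19 ± 2.59 to 170 ± 70.7 RPM) and TAAAAGTCAAGTAGGACTAATAAATAAGAT (0.444 to 33.2 RPM). With a spread estimated per group, 4150 sequences rose and 4813 fell, and 7996 calls were shared. Scaling to methylated spike-ins gave 175 rising and 19839 falling, scaling to all spike-ins 299 and 18972, edgeR with TMM 3076 and 7521 and DESeq2 3261 and 8807. Without the first replicate after oxidation at 10 ng the calls numbered 15230.

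By input, 4864 piRNA sequences rose and 7154 fell at 10 ng, 1312 and 781 at 50 ng and 434 and 491 at 100 ng. These counts depended on how the spread was shared, because the libraries after oxidation at 10 ng were the most variable. With a spread per group, 1265 rose and 3324 fell at 10 ng, 2676 and 1648 at 50 ng and 3543 and 2124 at 100 ng, and 4512 calls at 10 ng were shared. In data simulated with no change, the shared spread called 1089 of 22726 sequences at 10 ng and 0 at 50 and 100 ng. In the same data edgeR without TMM called 797 at 10 ng and 0 at 50 and 100 ng, and the spread per group called 0 at each input. Scaling to methylated spike-ins gave 442 and 17943 at 10 ng, 65 and 16761 at 50 ng and 21 and 16240 at 100 ng, and scaling to all spike-ins 526 and 17537, 110 and 14603, and 35 and 11903. At 50 ng the split was 888 and 940 after centring, 1998 and 2093 after quantile normalization, 504 and 660 by edgeR with TMM and 1018 and 2129 by DESeq2. At 100 ng it was 257 and 564, 702 and 1243, 139 and 440, and 455 and 1289 in the same order, and at 10 ng 2421 and 8085 by edgeR with TMM and 2972 and 8995 by DESeq2. Leaving out 1 library moved the count at 50 ng between 518 (without the second replicate before oxidation at 50 ng) and 6160 (without the second replicate after oxidation at 10 ng). At 100 ng it moved between 241 (without the second replicate before oxidation at 100 ng) and 3573 (without the second replicate after oxidation at 10 ng).

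Most tested piRNA sequences matched no annotated transcript. These 19610 sequences held 450161 ± 3450 RPM before and 505785 ± 50024 RPM after oxidation (n = 6), with 4235 called higher and 4383 lower. Sense matches to long non-coding transcripts (1985 sequences) went from 46421 ± 3047 to 53282 ± 9424 RPM, and those to protein-coding transcripts (489 sequences) from 7434 ± 101 to 8403 ± 825 RPM, each higher in 5 of 6 pairs. Sequences antisense to a transcript (457) went from 7582 ± 387 to 10288 ± 378 RPM, higher in 6 of 6 pairs. Averaged over inputs, the sums in these classes rose while the median members fell. The median log2 fold change was -0.11 without a match, -0.26 for long non-coding transcripts (382 called higher and 481 lower), -0.19 for protein-coding ones (94 and 123) and -0.11 for antisense sequences (103 and 94). In the same order the medians were -0.645, -0.789, -1.1 and -0.732 at 10 ng and 0.267, 0.171, 0.315 and 0.275 at 100 ng. At 100 ng the sums and the medians of these classes thus both rose. Sequences with matches in over 20 genes, a mark of repeats, went down from 3466 ± 547 to 1757 ± 234 RPM, with 7 of 113 called higher and 70 lower. Pseudogene matches (46 sequences) went from 833 ± 97.9 to 541 ± 164 RPM, and matches to miRNA precursors (26 sequences) from 587 ± 87.9 to 490 ± 73.6 RPM. The sums were not tested, and these directions hold in RPM, since scaling to methylated spike-ins turned most sequences to a fall. The loss of miRNA reads by itself also raises the RPM of all other reads. The sums rose 1.124-fold without a match, 1.148-fold for long non-coding transcripts, 1.13-fold for protein-coding ones and 1.357-fold for antisense sequences. All but the last were near the rise of the whole piRNA total, so they show no gain of these classes within it.

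Before oxidation, the miRNA profile at 10 ng differed from that at 100 ng, with 27 miRNAs higher and 49 lower at 10 ng (limma-trend, adjusted p below 0.05). The widest differences, chosen after their values were seen, were those of miR-125a-5p and miR-125b-5p, the mammalian relatives of lin-4. The first stood at 3099 RPM at 10 ng and 155 ± 5.41 RPM at 100 ng (n = 2 each, log2 difference 4.31 ± 0.44, SE, limma adjusted p = 9.48e-05), and the second at 2370 ± 3.08 and 245 ± 12.5 RPM (3.27 ± 0.33, adjusted p = 9.48e-05). At 50 ng they stood between these levels, at 460 and 592 RPM. Other miRNAs higher at 10 ng were miR-151-3p (52.7 ± 5.76 against 5.10 ± 0.54 RPM), miR-423-5p (351 ± 63.9 against 77.8 ± 4.87 RPM) and the Sertoli-list miR-202-3p (41.3 ± 8.88 against 8.81 ± 0.05 RPM). Lower at 10 ng were miR-148b-3p (30.3 ± 5.44 RPM against a mean above 200), miR-93-5p (11.9 ± 6.48 against 55.1 ± 4.60 RPM) and miR-449a-5p (8.09 ± 2.71 against 38.5 ± 1.56 RPM). In the lists, 4 higher and 9 lower were counted among 24 of the X-linked cluster, 3 and 1 among 9 of the let-7 family, 2 and 3 among 7 of the miR-10 and miR-125 family, 1 and 4 among 8 of the Sertoli list and 2 and 3 among 6 of the miR-17-92 clusters. Adjusted over the list alone, the called members numbered 13, 4, 5, 5 and 5, and camera called no list (adjusted p of 0.342 to 0.886). The split between higher and lower turned to 37 and 23 after centring, 14 and 13 after quantile normalization, 47 and 24 when scaled to all spike-ins, 40 and 39 when scaled to methylated ones, 42 and 33 by edgeR with TMM and 36 and 30 by DESeq2. Between 50 and 100 ng limma-trend called 0 miRNAs before oxidation, with 24 at an unadjusted p below 0.05, 19 with a spread per group, 16 by edgeR without TMM, 11 by edgeR with TMM and 35 by DESeq2.

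Among piRNA sequences before oxidation, 240 were higher and 169 lower at 10 ng than at 100 ng. With a spread per group these were 2388 and 2747, including all 409 of the former. The split was 2003 and 309 when scaled to all spike-ins and 1368 and 474 when scaled to methylated ones. Without 1 library the count ranged from 2 (without the first replicate before oxidation at 10 ng) to 3405 (without the second replicate after oxidation at 10 ng). Between 50 and 100 ng, 0 were called before oxidation by limma-trend, with 598 at an unadjusted p below 0.05, 797 with a spread per group, 0 by edgeR and 17 by DESeq2.

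After oxidation, the piRNA profile at 10 ng stood apart from those at 50 and 100 ng. The number of distinct piRNA sequences detected fell on oxidation from 217583 ± 7840 to 50953 ± 11808 at 10 ng, from 305197 ± 25264 to 171282 ± 4832 at 50 ng and from 324628 ± 483 to 199416 ± 15711 at 100 ng (n = 2 each). Over all 12 libraries the fall had an exact permutation p of 0.00926, the smallest possible, with an adjusted p of 0.0139 over 3 detection values. With a limit of 1 RPM the log2 change was -0.36 (exact permutation p = 0.324) and with a limit of 10 RPM it was 0.66. The number of miRNAs detected fell from 334.5 ± 30.0 to 65.8 ± 4.36 (n = 6, adjusted p = 0.0139, permutation test). Log2 piRNA abundance correlated between replicates across 22726 sequences, which are not independent, with Pearson's r of 0.886, 0.930 and 0.937 before oxidation at 10, 50 and 100 ng and of 0.470, 0.778 and 0.884 after it. Between before and after, r was 0.108 at 10 ng, 0.635 at 50 ng and 0.755 at 100 ng. Across 141 miRNAs, r between replicates was 0.988, 0.996 and 0.994 before oxidation and 0.805, 0.823 and 0.897 after it. The share of thinned piRNA reads in the 100 most abundant sequences was 11.3% ± 1.27 before and 10.9% ± 2.94 after oxidation (n = 6, exact permutation p = 0.583).

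**Figure D5:**
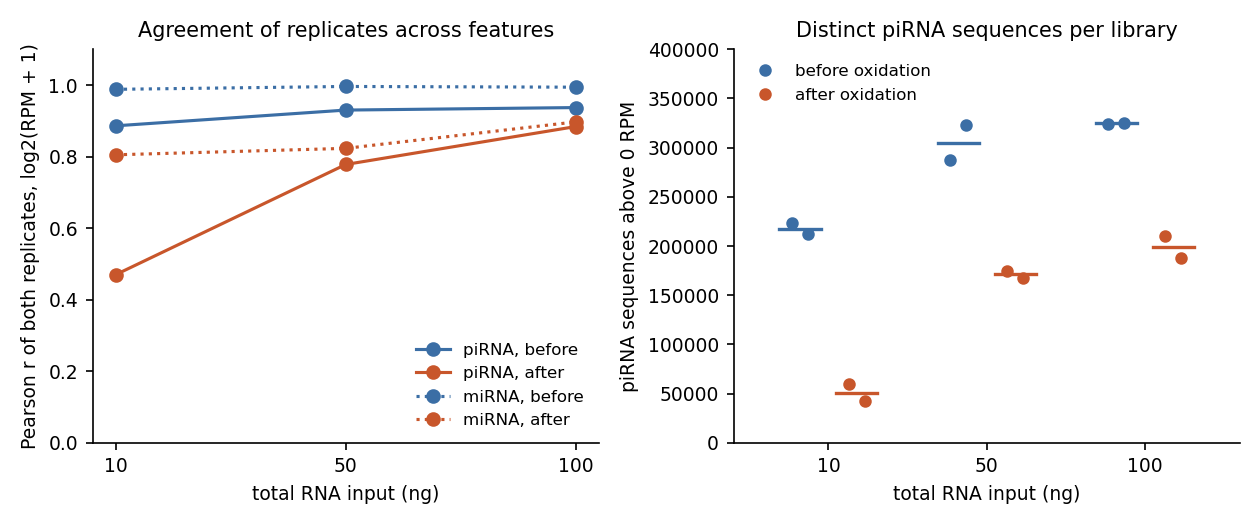
Left, Pearson's r of log2(RPM + 1) between the 2 replicates of each group, across 22726 piRNA sequences (solid) and across the tested miRNAs (dotted). Right, distinct piRNA sequences per library, with lines at means of 2. After oxidation the 10 ng libraries hold 42603 and 59302 sequences and have a piRNA r of 0.470, the lowest of the 6 groups.

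After oxidation, 2850 piRNA sequences were higher and 6548 lower at 10 ng than at 100 ng (limma-trend). With a spread per group these were 127 and 2801, with 2848 calls shared. In data simulated with no change, the shared spread called 1122 sequences in this comparison, edgeR without TMM 793 and the spread per group 0. The split was 3563 and 4104 after quantile normalization, 539 and 8355 with all spike-ins, 482 and 8219 with methylated ones, 656 and 7138 by edgeR with TMM and 1617 and 7546 by DESeq2. Among the named piRNAs, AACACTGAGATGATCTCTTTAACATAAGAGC stood at 616 RPM at 10 ng and 5202 RPM at 100 ng. Without the first replicate after oxidation at 10 ng the count was 15589. Between 50 and 100 ng 0 were called, with 1666 at an unadjusted p below 0.05, 30 with a spread per group, 0 by edgeR and 157 by DESeq2. Among miRNAs after oxidation, miR-30a-5p (log2 difference -1.50, limma adjusted p = 0.0289) and miR-99b-5p (-1.91, adjusted p = 0.0086) were lower at 10 ng than at 100 ng. Both were also lower at 50 ng (-1.84 and -1.53), where miR-375-3p (1.91) and the -3p arms of miR-465a, miR-465b and miR-465c, which share their reads (0.77 each), were higher. These levels rested on few reads, with 38 for miR-30a-5p and 81 for miR-99b-5p over the 6 libraries, and the counts of 2 and 6 moved to between 1 and 9 and between 0 and 14 without 1 library. The count of 2 was highest without the second, and that of 6 without the first, replicate after oxidation at 100 ng.

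The oxidation effect differed between inputs for 47 of 141 miRNAs and 5250 of 22726 piRNA sequences (limma-trend moderated F test, adjusted p below 0.05). Between 10 and 100 ng alone, 52 miRNAs differed, 34 with a higher log2 fold change at 10 ng and 18 with a lower one. The smallest p values were those of miR-202-3p (-2.09 ± 0.21, SE, at 10 against 100 ng), miR-148b-3p (2.89 ± 0.30) and miR-203-3p (1.5 ± 0.20), with limma adjusted p of 0.000543, 0.000543 and 0.00116 for this difference and of 0.00144, 0.00144 and 0.00335 in the F test. After oxidation these stood at 0, 2 and 2 reads over 6 libraries, so the differences followed the levels before oxidation, with miR-203-3p at 35.5 ± 2.90 RPM at 10 ng and 68.6 ± 9.87 RPM at 100 ng. The split was 15 and 31 after centring, 15 and 51 with all spike-ins, 25 and 41 with methylated ones and 2 and 6 by DESeq2, and edgeR called 0 with or without TMM, against 75 by limma at an unadjusted p below 0.05. For piRNA sequences, 1796 had a higher and 4793 a lower log2 fold change at 10 ng than at 100 ng. With a spread per group these were 311 and 2634, with 2491 calls shared, and without 1 library the count ranged from 3933 to 13380. The split was 1628 and 2230 after quantile normalization, 395 and 8448 with all spike-ins, 517 and 7191 with methylated ones, 677 and 6120 by edgeR with TMM and 1184 and 6781 by DESeq2.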

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

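All tests of explanations in this part were chosen after the results were seen, while the interaction tests were planned. The results below are listed because the effect of oxidation differed between inputs. No explanation in terms of the animals was tested, since the labels give 1 strain, sex and age and technical replicates.

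For miRNAs, the effect of oxidation differed between inputs for 47 by the F test and for 52 between 10 and 100 ng. Among the named miRNAs that passed either test, the log2 effect at 10 ng minus that at 100 ng was 2.89 for miR-148b-3p, 1.5 for miR-203-3p, 1.96 for miR-7214-5p, 1.05 for miR-183-5p, 1.02 for miR-10b-5p, 0.64 for miR-29a-3p and 0.52 for miR-127-3p. It was -3.73 for miR-151-3p, -3.63 for miR-7217-3p, -2.09 for miR-202-3p, -1.46 for miR-92a-3p, -1.18 for miR-99b-5p and -0.55 for miR-34b-3p. The -0.60 of miR-30a-5p passed the F test but not the test between 10 and 100 ng (limma adjusted p = 0.22), while miR-7214-5p, miR-7217-3p and miR-92a-3p passed the latter alone. Of the 52, 48 lay below 5 RPM after oxidation. Across 141 miRNAs the interaction from 1 replicate correlated with the difference before oxidation in the other replicate at -0.78 and -0.66, and with the difference after oxidation at 0.13 and 0.20. Of the 52 interactions, 51 had the opposite sign to the difference before oxidation. The interaction contains that difference with its sign reversed, so with values near 0 after oxidation such correlations and signs follow by arithmetic. They are not separate support for an explanation. Input differences before oxidation, with values near 0 after it, may account for interactions among the 48, but not for that of miR-99b-5p. Its interaction had the same sign as its difference before oxidation (-0.735), and its difference after oxidation was larger (-1.91). The other 4 of the 52 (miR-10b-5p, miR-468-5p, miR-7214-5p and miR-7217-3p) lay higher after oxidation and stay open. Why the libraries at 10 ng differed before oxidation stays open.

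For piRNA sequences, the effect differed between inputs for 5250 by the F test and for 6589 between 10 and 100 ng. The difference was -3.57 for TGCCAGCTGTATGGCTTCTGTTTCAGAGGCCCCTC, -2.13 for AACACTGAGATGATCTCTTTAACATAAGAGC, -1.21 for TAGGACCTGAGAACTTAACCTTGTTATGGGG and -1.11 for TACCTCGGTCTCTGTAGAATCCAGTTTTT. It was 3.36 for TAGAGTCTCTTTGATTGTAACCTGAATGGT and 3.09 for CCCCACGTTGGGCGCCA. In 4 further values the libraries moved in opposite directions at different inputs, and these differences were not tested. The share under 26 nt changed by 2.50 percentage points at 10 ng and -0.50 at 100 ng, the 24-nt share by 0.087 at 10 ng and -0.058 at both 50 and 100 ng, and the 31-nt share by -1.18, 0.535 and 0.859 at 10, 50 and 100 ng. The share of the 100 most abundant sequences changed by -2.08 at 10 ng and 1.37 at 100 ng.

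The piRNA libraries after oxidation at 10 ng held fewer distinct sequences and agreed less than the others. A lower depth does not account for it, since with all libraries thinned to the same number of piRNA reads the log2 change at 10 ng was still -2.02, nor do a few dominant sequences, since the share of the 100 most abundant fell by 2.08 percentage points. The chi-square per degree of freedom between the replicates was 26.7 at 10 ng after oxidation, against 8.12 at 50 ng and 4.62 at 100 ng. For sequences of 20 to 60 reads and for those of 500 or more it was 26.6 and 27.0 at 10 ng (24.2 and 33.9 after thinning), 6.16 and 43.9 at 50 ng and 4.42 and 7.43 at 100 ng. Few molecules read many times each would raise it alike at all read numbers, which remains a candidate explanation at 10 ng but would not give the uneven values at 50 ng, and molecules were not counted.

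The number of piRNA reads per methylated spike-in read fell on oxidation. No single spike-in accounts for it, since the smallest of the 3 falls was -2.13 on the log2 scale. A loss of unmethylated sequences of other lengths does not account for it, since 13969 sequences of 29 to 32 nt with a 5' U had a median of -2.49 when scaled to methylated spike-ins, and 94.5% of them were negative. Whether the spike-ins are recovered differently from cellular RNA cannot be told apart from a loss of piRNAs. Their rises at 10 ng differed by 6.77 times among the 3, where the rise of sp1Me rested on 39 and 30 reads before oxidation. The rises differed less at 100 ng, at 5.62-fold for sp1Me, 5.66-fold for sp2Me and 2.63-fold for sp3Me. At neither input do the 3 form 1 common scale.

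The number of calls after against before oxidation was compared with that in other splits of the libraries. Of 100 splits of the 12 libraries within inputs, the real one included, only the real one called as many. It called 139 miRNAs against at most 135 in another split and 10008 piRNA sequences against at most 7628. By themselves these counts do not exclude chance. A split that swaps the labels of 1 whole input keeps part of the oxidation difference, and the miRNA count lies near its limit of 141.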

How the results depend on the processing

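The scaling to methylated spike-ins, edgeR without TMM, the spread per group, the thinning, the piRNA total per reads other than miRNA reads and the estimated correlation on centred values were chosen after the data were seen, and the other settings before. Of 27 values of class totals, spike-ins, composition and detection under these settings, 20 kept their direction and their side of the threshold. Of 290 counts of calls, 170 stayed within 1.5 times and 120 did not. Of 533 values of named miRNAs, 419 kept direction and side, 55 lost the call, 10 gained it and 49 reversed. Of 154 values of named piRNA sequences, 138 kept both, 4 gained a call and 12 reversed. The class totals kept direction and p without the 5 highest features, at -8.05 (log2) for miRNA RPM and 0.17 for piRNA RPM. Per reads other than miRNA reads the log2 change of the piRNA total turned to -0.022, since RPM counts the lost miRNA reads in its total. Unless stated, the cause of a change was not tested.

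Scalings and count models moved many miRNA results. In miRNAs the loss was common to nearly all, and centring and quantile normalization, which set the median or the whole distribution equal between libraries, take a common loss out by construction. TMM and the size factors of DESeq2 assume that most features are unchanged, so they also take out some or all of a common loss. Rises under these settings are therefore no evidence against the loss. The median log2 fold change of tested miRNAs was -6.02 in RPM, 0.19 after centring, -0.16 after quantile normalization, 0.73 by DESeq2, -4.16 by edgeR with TMM, -9.36 by edgeR without it, -7.43 with all spike-ins and -7.61 with methylated ones, so edgeR with TMM lost most calls while a fall remained. By edgeR with TMM the median was -1.40 at 10 ng, -6.88 at 50 ng and -2.16 at 100 ng. By DESeq2 the miRNA calls numbered 27 for oxidation averaged over inputs, 14 for oxidation at 10 ng, 22 for oxidation at 50 ng, 27 for oxidation at 100 ng, 8 for the 10 against 100 ng interaction, 4 for 10 against 100 ng after oxidation, 35 for 50 against 100 ng before oxidation and 10 for 50 against 100 ng after oxidation. Among piRNA sequences the calls numbered 3147 for oxidation at 50 ng, 1744 for oxidation at 100 ng, 1429 for 10 against 100 ng before oxidation, 17 for 50 against 100 ng before oxidation and 157 for 50 against 100 ng after oxidation. The reversed log2 fold changes were -0.63 for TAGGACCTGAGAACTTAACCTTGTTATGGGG, -0.65 for TATGTGAATTTCAACTGTTGGCTCCACAGG, 0.41 for miR-148b-3p, 3.24 for miR-151-3p, 0.39 for miR-16-5p, 1.88 for miR-202-3p, 1.09 for miR-203-3p, 0.10 for miR-25-3p, 1.31 for miR-27b-3p, 1.20 for miR-29a-3p, 1.03 for miR-30c-5p, 8.89 for miR-3470a, 8.41 for miR-3470b, 8.84 for miR-3471, 0.15 for miR-34c-5p, 5.67 for miR-3535, 0.73 for miR-541-5p, 6.59 for miR-7217-3p and 0.55 for miR-92a-3p.

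By edgeR with TMM the miRNA calls numbered 21 for oxidation averaged over inputs, 9 for oxidation at 10 ng, 20 for oxidation at 50 ng, 19 for oxidation at 100 ng, 0 for the interaction F test, 0 for the 10 against 100 ng interaction, 11 for 50 against 100 ng before oxidation and 0 for 50 against 100 ng after oxidation. For piRNA sequences there were 1164 for oxidation at 50 ng and 579 for oxidation at 100 ng. The reversed log2 fold changes were -0.49 for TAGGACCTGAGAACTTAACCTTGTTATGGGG, -0.50 for TATGTGAATTTCAACTGTTGGCTCCACAGG, 0.89 for miR-27b-3p, 0.61 for miR-30c-5p, 8.47 for miR-3470a, 8.02 for miR-3470b, 8.37 for miR-3471, 5.19 for miR-3535, 6.12 for miR-7217-3p and 0.13 for miR-92a-3p. By edgeR without TMM the miRNA calls numbered 0 for the interaction F test, 0 for the 10 against 100 ng interaction, 16 for 50 against 100 ng before oxidation and 2 for 50 against 100 ng after oxidation. The interaction of 10 against 100 ng had 75 miRNAs at an unadjusted p below 0.05 by limma.

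After quantile normalization the miRNA calls numbered 82 for oxidation averaged over inputs, 48 for oxidation at 10 ng, 59 for oxidation at 50 ng, 58 for oxidation at 100 ng, 17 for the interaction F test, 11 for the 10 against 100 ng interaction, 27 for 10 against 100 ng before oxidation and 1 for 10 against 100 ng after oxidation. Called piRNA sequences numbered 4091 for oxidation at 50 ng, 1945 for oxidation at 100 ng, 2749 for the interaction F test, 3858 for the 10 against 100 ng interaction and 1261 for 10 against 100 ng before oxidation. The reversed log2 fold changes were -0.12 for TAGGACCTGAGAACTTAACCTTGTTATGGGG, -0.25 for TATGTGAATTTCAACTGTTGGCTCCACAGG, 0.88 for miR-151-3p, 0.38 for miR-202-3p, 0.16 for miR-203-3p, 0.32 for miR-27b-3p, 0.093 for miR-29a-3p, 6.18 for miR-3470a, 4.23 for miR-3470b, 5.51 for miR-3471, 2.84 for miR-3535 and 3.70 for miR-7217-3p.

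After centring the miRNA calls numbered 3 for 50 against 100 ng after oxidation. The reversed log2 fold changes were -0.16 for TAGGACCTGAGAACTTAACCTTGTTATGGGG, -0.17 for TATGTGAATTTCAACTGTTGGCTCCACAGG, 2.42 for miR-151-3p, 2.04 for miR-202-3p, 0.70 for miR-203-3p, 1.40 for miR-29a-3p, 5.18 for miR-3470a, 4.57 for miR-3470b, 4.86 for miR-3471, 2.42 for miR-3535, 0.58 for miR-541-5p and 3.0 for miR-7217-3p. The miRNA calls for oxidation averaged over inputs shared 127 with the main setting after centring, 62 of them with the same sign. They shared 80 and 48 after quantile normalization, 19 and 15 by edgeR with TMM, 25 and 10 by DESeq2, and 138 and 137 with either spike-in scaling.

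The median log2 fold change of piRNA sequences was -0.14 in RPM, -2.59 with methylated spike-ins, -2.31 with all spike-ins, -0.49 by edgeR with TMM, -0.64 by DESeq2, -0.34 after centring and -0.05 after quantile normalization. Scaled to all spike-in reads the miRNA calls numbered 23 for 50 against 100 ng before oxidation. The piRNA calls numbered 19271 for oxidation averaged over inputs, 18063 for oxidation at 10 ng, 14713 for oxidation at 50 ng, 11938 for oxidation at 100 ng and 2312 for 10 against 100 ng before oxidation. The reversed log2 fold changes were -2.61 for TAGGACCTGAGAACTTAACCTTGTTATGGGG, -2.62 for TATGTGAATTTCAACTGTTGGCTCCACAGG, -1.77 for miR-5099 and -1.95 for miR-7214-5p.

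Scaled to methylated spike-in reads the miRNA calls numbered 17 for 50 against 100 ng before oxidation. Among piRNA sequences the calls numbered 20014 for oxidation averaged over inputs, 18385 for oxidation at 10 ng, 16826 for oxidation at 50 ng, 16261 for oxidation at 100 ng and 1842 for 10 against 100 ng before oxidation. The reversed log2 fold changes were -2.94 for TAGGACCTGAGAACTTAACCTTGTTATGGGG, -2.96 for TATGTGAATTTCAACTGTTGGCTCCACAGG, -2.06 for miR-5099 and -2.27 for miR-7214-5p.

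The spread assumed for each group moved the piRNA counts, and the libraries after oxidation at 10 ng were the most variable. With a spread per group the miRNA calls numbered 19 for 50 against 100 ng before oxidation and 3 for 50 against 100 ng after oxidation. For piRNA sequences there were 4589 for oxidation at 10 ng, 4324 for oxidation at 50 ng, 5667 for oxidation at 100 ng, 1821 for the interaction F test, 2945 for the 10 against 100 ng interaction, 5135 for 10 against 100 ng before oxidation, 2928 for 10 against 100 ng after oxidation, 797 for 50 against 100 ng before oxidation and 30 for 50 against 100 ng after oxidation. With only the 4 libraries compared the miRNA calls numbered 0 for 10 against 100 ng after oxidation, 42 for 50 against 100 ng before oxidation and 0 for 50 against 100 ng after oxidation. Called piRNA sequences numbered 7666 for oxidation at 10 ng, 3864 for oxidation at 50 ng, 5207 for oxidation at 100 ng, 4816 for 10 against 100 ng before oxidation, 5639 for 10 against 100 ng after oxidation and 786 for 50 against 100 ng before oxidation.

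Without a filter the miRNA calls numbered 298 for oxidation averaged over inputs, 214 for oxidation at 10 ng, 233 for oxidation at 50 ng, 263 for oxidation at 100 ng, 115 for 10 against 100 ng before oxidation, 18 for 50 against 100 ng before oxidation and 1 for 50 against 100 ng after oxidation. The piRNA calls numbered 6094 for oxidation at 10 ng, 205 for oxidation at 50 ng, 114 for oxidation at 100 ng, 525 for the interaction F test, 669 for the 10 against 100 ng interaction, 101 for 10 against 100 ng before oxidation, 2806 for 10 against 100 ng after oxidation, 3 for 50 against 100 ng before oxidation and 2 for 50 against 100 ng after oxidation.

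With a filter of 50 RPM the miRNA calls numbered 66 for oxidation averaged over inputs, 66 for oxidation at 10 ng, 66 for oxidation at 50 ng, 66 for oxidation at 100 ng, 17 for the interaction F test, 18 for the 10 against 100 ng interaction, 26 for 10 against 100 ng before oxidation and 2 for 50 against 100 ng before oxidation. Among piRNA sequences the calls numbered 1102 for oxidation averaged over inputs, 1386 for oxidation at 10 ng, 547 for oxidation at 50 ng, 467 for oxidation at 100 ng, 930 for the interaction F test, 1113 for the 10 against 100 ng interaction and 1283 for 10 against 100 ng after oxidation. With a pseudocount of 0.1 the miRNA calls numbered 21 for the interaction F test, 18 for the 10 against 100 ng interaction, 38 for 10 against 100 ng before oxidation, 4 for 10 against 100 ng after oxidation and 10 for 50 against 100 ng after oxidation. With a pseudocount of 10 the miRNA calls numbered 96 for the interaction F test, 95 for the 10 against 100 ng interaction, 40 for 50 against 100 ng before oxidation and 2 for 50 against 100 ng after oxidation. For piRNA sequences there were 730 for 10 against 100 ng before oxidation. With an added limit of 1 on the absolute log2 fold change the miRNA calls numbered 39 for 10 against 100 ng before oxidation and 3 for 50 against 100 ng after oxidation.

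With the replicate block the miRNA calls numbered 1 for 10 against 100 ng after oxidation and 3 for 50 against 100 ng after oxidation. Called piRNA sequences numbered 4339 for oxidation averaged over inputs and 2.2e+02 for 10 against 100 ng before oxidation. The oxidation calls of miR-7214-5p and miR-3470a were lost (adjusted p = 0.122 and 0.0585 by limma). Of the 4339, 2582 rose and 1757 fell. The replicate numbers do not pair the libraries, since deviations of same-numbered libraries before and after oxidation correlated at 0.041, 0.002 and -0.133 across miRNAs and at -0.008, -0.013 and 0.01 across piRNA sequences.

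In composition, counting distinct sequences unweighted turned the change under 26 nt to -4.57 points and that of 26 to 28 nt to 0.70. Among sequences of at least 5 RPM, the change under 26 nt was 2.34 and passed the threshold, and that of 29 to 32 nt was 0.16 and did not. The log2 change in detected piRNA sequences was -0.36 at a limit of 1 RPM, 0.66 at a limit of 10 RPM and -1.09 after thinning. Of the miRNA lists, camera called 0, with either correlation, fry called 10, and camera on centred values called 2 with the preset and 0 with an estimated correlation.

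Leaving out 1 library at a time assumes that the lone library of a group varies like the other groups. Of 240 counts, 170 stayed within 1.5 times. The miRNA counts ranged from 31 to 55 for the interaction F test, from 1 to 9 for 10 against 100 ng after oxidation, from 0 to 13 for 50 against 100 ng before oxidation and from 0 to 14 for 50 against 100 ng after it. The lowest F test count came without the second replicate after oxidation at 10 ng, and the highest of the other 3 without the second replicate after oxidation at 100 ng, the first before oxidation at 10 ng and the first after oxidation at 100 ng.

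The piRNA counts without 1 library ranged from 8187 to 15230 for oxidation averaged over inputs, from 518 to 6160 at 50 ng and from 241 to 3573 at 100 ng. They ranged from 3154 to 12549 for the interaction F test, from 3933 to 13380 for the 10 against 100 ng interaction, from 2 to 3405 for 10 against 100 ng before oxidation and from 6499 to 15589 after it. For 50 against 100 ng the ranges were 0 to 49 before oxidation and 0 to 331 after it. Every one of these highest counts came without a library after oxidation at 10 ng, the first replicate for oxidation averaged over inputs, both interactions and 10 against 100 ng after oxidation, and the second for the others.

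Without 1 replicate number the change under 26 nt ranged from 0.237 to 1.04 points. Without 1 library 136 of the 139 miRNA calls for oxidation averaged over inputs held in every fit. The calls of miR-7214-5p, miR-3470a and miR-3470b were lost in 10, 9 and 10 of 12 fits, with adjusted p up to 0.124, 0.106 and 0.09, and all 3 were lost with a pseudocount of 0.1 and without a filter. The log2 fold change of miR-5099 ranged from -0.12 (without the first replicate after oxidation at 10 ng) to 0.93 (without the second). That of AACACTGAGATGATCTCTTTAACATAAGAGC ranged from -0.15 to 0.065, that of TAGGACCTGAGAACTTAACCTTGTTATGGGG from -0.038 to 0.12 and that of TATGTGAATTTCAACTGTTGGCTCCACAGG from -0.015 to 0.08, each lowest without the first and highest without the second replicate after oxidation at 50 ng.

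The number of miRNA reads limits the miRNA values after oxidation, at 625 to 937 per library, so differences between inputs among them rest on few reads.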

Other observations

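All tests and sums in this part were chosen after the data were seen.

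Of the 25 annotated genes with the most piRNA RPM before oxidation, 16 were lincRNAs and 4 were protein-coding. Their piRNA sequences were summed, and in RPM averaged over inputs 7 rose, 4 fell and 14 did neither (exact permutation tests within inputs, adjusted over the 25). Some of the 14 moved in opposite directions at different inputs. The highest was Gm21269, a lincRNA on chromosome 7 (73816546 to 73838898, plus strand), whose 322 sequences went from 11014 ± 1603 to 13239 ± 1651 RPM (n = 6, adjusted p = 0.0231, higher in 6 of 6 pairs). It lies 42 bases from Gm10619 on the opposite strand (73781429 to 73816503), whose 124 sequences went from 3329 ± 496 to 4429 ± 1554 RPM (permutation test, adjusted p = 0.0827, higher in 4 of 6 pairs). The piRNAs of the lincRNA 1700001L05Rik on chromosome 15 had 5723 ± 828 and 7296 ± 2792 RPM (permutation test, adjusted p = 0.173, 4 of 6 pairs). By input, those of 1700001L05Rik went from 4774 to 4150 RPM at 10 ng and from 6604 to 10245 RPM at 100 ng. Those of Gm10619 went from 2746 to 2623 RPM at 10 ng and from 3828 to 5889 RPM at 100 ng. The sums of Cbl (495 to 899 RPM), 4933440M02Rik (1060 to 1723 RPM) and Tbl2 (1071 to 1495 RPM) rose in 6 of 6 pairs, and those of Gm21221 (995 RPM before, log2 effect -1.06) and Zfp389 (399 to 224 RPM) fell in 6 of 6 (permutation test, adjusted p = 0.0231 each). The loss of miRNA reads by itself raises the RPM of all other reads. It thus favours calls of a rise and adds to small effects such as that of Gm21269 (log2 effect 0.27). Per methylated spike-in read all 25 fell, by 2.14 to 4.05 on the log2 scale.

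A region of chromosome 17 held both Gm10505 and Gm49794. Sequences of Gm10505 (27325035 to 27344833, plus strand) went from 2004 ± 279 to 1291 ± 147 RPM (n = 6, permutation test, adjusted p = 0.0231, lower in 6 of 6 pairs). Those of the neighbouring lincRNA Gm49794 (27354111 to 27367492, plus strand) had 4299 ± 139 and 4356 ± 238 RPM (permutation test, adjusted p = 0.620, higher in 4 of 6 pairs). The hairpin of miR-7217 (27355738 to 27355799) lies inside Gm49794, and that of miR-7214 (27317035 to 27317095) lies upstream of Gm10505 on the opposite strand.

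Some miRNA entries that kept their level may hold reads of piRNAs from the same hairpins. Of 126 tested miRNAs with a hairpin transcript, 7 had 5 or more matching sequences of at least 24 nt in the piRNA table, namely miR-468, miR-7214, miR-3470a, miR-3471, miR-3470b, miR-7210 and miR-7217. Their median log2 fold change was -1.34 against -5.67 for the other 119, a difference of 4.32. They made up 6 of the 7 highest log2 fold changes (Fisher's exact p = 9.9e-09). The exception among the high entries was miR-5099, with a log2 fold change of 0.40 and no such sequences.

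The 19-nt sequences that fell may include products of piRNA-guided cleavage without a methylated 3' end. Such products would pair with a guide from its base 11 onwards. Among 98738 guides of 24 to 33 nt, 697 sequences of 19 nt paired from base 11, against at most 217 at any other offset, a ratio of 3.21. At 20, 18 and 21 nt, 57, 31 and 9 paired from base 11, against at most 31, 20 and 18 at any other offset. Base 11 was thus also the most frequent start at 18 and 20 nt. The search kept only sequences of at least 0.2 RPM before oxidation, which favours a fall. Under this filter the 697 went from 884.7 to 17.5 RPM in sum, the 539 that paired only at other offsets from 448.4 to 20.1 RPM and the 5719 that paired with no guide from 5286.8 to 3284.9 RPM, while the sums at 18, 20 and 21 nt rose to 2759.5, 4015.3 and 3511.1 RPM from 1373.4, 2300.8 and 2794.8 RPM. The fall was thus not specific to base 11, and these sums were not tested. Before oxidation 43.0% of 19-nt RPM started with U, and 81.9% after it, while the other lengths of 17 to 22 nt had 82.4% to 86.0% before. A few dominant sequences do not account for the fall, since without the 100 most abundant the log2 change of the 19-nt share was -1.24, against -0.93 with them.

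Short sequences ending in CCA, the end added to mature tRNAs, took a larger share after oxidation. Among sequences of 17, 18 and 20 to 22 nt their share went from 3.57% ± 0.42 to 7.01% ± 1.33 (n = 6), a rise of 3.44 percentage points (exact permutation p = 0.00926, the smallest possible). Each library after oxidation lay at least 2.4 points above those before it at its input. Whether tRNA 3' fragments resist oxidation cannot be told from this. The tRNA genes were not searched, so the origin of these 758 sequences is not shown, and other 3' ends were not compared. Periodate blocks ends with free hydroxyls, so such fragments would need a protected 3' end to resist, which was not measured. Longer members of families of sequences with a shared 5' end had slightly lower log2 fold changes than shorter ones, with a slope per base of -0.03 ± 0.02 (SD over 6 pairs of libraries, negative in 6 of 6), and in 53.4% of 4890 families the longest member had the lower value. Among members with the same 3' base the slope was -0.025 ± 0.027 (negative in 5 of 6 pairs). At 10, 50 and 100 ng it was -0.06, -0.014 and -0.002, against -0.054, -0.024 and -0.012 among all members. By 3' base it ranged from 0.001 for A to -0.068 for G. The 3' base does not account for the whole slope at 10 ng, where the slope was no smaller with the base fixed (SD 0.003 over 2 pairs), nor at 50 ng, where it was smaller but still negative in both pairs (SD 0.001). At 100 ng an effect of the 3' base cannot be told apart from one of length, because the slope with the base fixed lay within its spread (SD 0.004).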
